A study of Mus musculus with 9 samples.

How the data were processed

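Heart RNA was measured in 18 mouse libraries, 3 Klf9KI and 3 Wt-Cre at each of 1, 4 and 8 weeks, and Klf9-bound chromatin in 1 sham and 1 TAC library from mice of 12 to 14 weeks, with TAC lasting 2 weeks and a pooled input, per the labels. The titles call the RNA total RNA, and the labels' protocols describe poly-A selection. The protocols name both a stranded and an unstranded library type and do not say which was used. Counts of overlapping antisense genes and of near-identical gene copies are therefore uncertain.

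The authors deposited 1 gene table per age. Its count columns hold raw counts per gene and mouse, per the file headers, and they were the values tested here. A second set of deposited columns holds a normalised signal, which equalled each count divided by 1 size factor per library. The deposited FPKM columns, per the file headers, were not used here. The authors' log2 fold changes and p-values came from their own test, per the file headers. At an adjusted p under 0.05 the authors' table held 522 genes at 1 week, 2165 at 4 weeks and 2032 at 8 weeks, and gave Klf9 a log2 fold change of 3.27, 0.37 and 1.19. The submitters' processing notes name fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0, BWA and MACS2 2.1.0 and the build mm10, without options. For chromatin the authors deposited 1 table of merged regions with a mean signal and a presence call per region and library, and the log2 ratio of TAC to sham, per the file headers. The genes and CpG islands of each region were assigned by the authors. How that signal was scaled between sham and TAC is not stated.

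Gene identifiers and symbols were those of the tables. Of the identifiers 26206 of 26234, 24196 of 24222 and 30036 of 30074 matched the reference name table at 1, 4 and 8 weeks, and 23, 23 and 25 symbols that a spreadsheet had turned into dates were restored by identifier. Of 6868 region symbols 6700 matched a gene. Coordinates are those of the deposited tables.

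Each age was tested alone with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM normalisation, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences between ages and the changes within Wt-Cre hearts came from 1 fit of all 18 libraries over the 21463 genes present in all 3 tables, of which 16660 were tested. Age and any sequencing batch that followed age cannot be told apart in that fit. A total of 38 gene lists with 806 genes, fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry. Lists of fewer than 3 measured members were not tested. List tests on the 18-library contrasts were added after seeing the data. CPM values were computed with edgeR on the effective library size within each age, except where ages are compared, which used the fit of 18 libraries. Errors are SD over 3 hearts or SE of the fitted log2 fold change. Shares of genes with a Klf9 region were compared with Fisher's exact test, two-sided, in scipy 1.17.1 under Python 3.11.15, against genes tested and not called, and stratified for expression and length with statsmodels 0.14.6. Genes are not independent samples in these tests. A fold against a group without counts was bounded with 3 counts over the group.

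Named genes followed a rule set in advance. At each age it took Klf9, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among genes past the threshold, with at least 5 CPM in the higher group and no overlap between the mice, and up to 4 members of each list by adjusted p. Nppa, Nppb, Myh6, Myh7, Atp2a2, Ppargc1a and Cpt1b were added where their list is described. For differences between ages it took 5 genes each way, and for chromatin the 10 regions with the highest sham value and the regions of genes named for RNA. Of the genes so chosen 2 are not reported here. Xist, Eif2s3y, Myl7, Gt(ROSA)26Sor and the genes called at all 3 ages were named after their values were seen.

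Alternatives fixed in advance were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 1 CPM in 3 libraries, protein-coding genes alone, a limit of 2-fold, all 18 libraries in 1 fit, a block on the replicate number, each library left out in turn, and for regions those within 1 kb of a gene start, the upper part by signal, a matched background and a limit of 1.5-fold. Added after seeing the data were sex as a covariate, leaving out the 2 libraries that carried Xist, the level of Myl7 as a covariate, leaving out mitochondrial genes, and a DESeq2 background that kept genes without an adjusted p.

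Each step was tested on simulated data first. With 1.5-, 2- and 4-fold changes in 200 genes the test recovered 38.8, 62.7 and 77.3% at 1 week (15367 genes, 9 false of 128 calls), 13.4, 59.7 and 95.5% at 4 weeks (14218 genes, 7 of 119) and 1.49, 28.4 and 68.2% at 8 weeks (14109 genes, 3 of 68). For differences between ages it recovered 0, 10.4 and 56.1% from 1 to 4 weeks (16153 genes), 2.99, 4.48 and 54.5% from 4 to 8 weeks (16188 genes) and 0, 8.96 and 63.6% from 1 to 8 weeks (16137 genes), with 0 false calls in each. For Wt-Cre ages it recovered 4.48, 41.8 and 75.8% from 1 to 4 weeks (16180 genes, 3 false of 84) and 11.9, 37.3 and 77.3% from 4 to 8 weeks (16121 genes, 6 of 90). A list moved 1.5-fold was called with the preset correlation at all 3 ages, with 1 other list called at 1 week, and was missed at 8 weeks with the estimated correlation and with fry. Simulated genes were drawn independently, while the real complex I list had an estimated correlation of 0.626 at 1 week. The simulation therefore cannot show how often lists of correlated genes are called falsely. A simulated odds ratio of 3 for regions was read as 3.11 and one of 1 as 0.909 (13928 genes).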

Results

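Hearts of mice that express Klf9 constitutively in cardiomyocytes (Klf9KI, which carry the alphaMHC-Cre driver and a Klf9 knock-in) were compared with hearts that carry the driver alone (Wt-Cre). RNA was sequenced at 1, 4 and 8 weeks of age, with 3 libraries in each of the 6 groups. The titles call it total RNA and the protocols describe poly-A selection. Klf9 is a zinc-finger transcription factor of the Krüppel-like family whose gene is induced by glucocorticoids. The summed gene counts ran from 17225388 to 32855383 per library at 1 week, from 12086856 to 14890828 at 4 weeks and from 12543825 to 19912542 at 8 weeks. The titles give n = 3 for each group but no litter and no sex, so the p-values reflect the spread between these samples. In a separate part of the study, chromatin bound by Klf9 was precipitated from sham-operated adult hearts and from hearts after transaortic constriction (TAC), which loads the left ventricle with pressure. Each condition had 1 library.

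Klf9 itself (ENSMUSG00000033863, mm10 chromosome 19, 23141226 to 23166911) was read first in every library. At 1 week it stood at 192.9, 222.0 and 182.8 CPM (counts scaled by library within each age) in the 3 Klf9KI hearts. In the 3 Wt-Cre hearts it stood at 23.2, 21.9 and 17.2 CPM. Klf9 rose in Klf9KI hearts at that age by 3.26 on the log2 scale (SE 0.13, adjusted p = 3.55e-09), from 20.8 ± 3.18 to 199 ± 20.3 CPM (SD, n = 3). At 4 weeks the levels were 143.2, 178.9 and 167.4 CPM in Klf9KI and 112.9, 142.5 and 123.2 CPM in Wt-Cre hearts, and the difference of 0.37 (SE 0.14) did not pass the test (adjusted p = 0.111). A block on the replicate number, which the labels tie to nothing else, left it at 0.37 and past the threshold (adjusted p = 0.0311). At 8 weeks they were 108.1, 121.8 and 111.3 against 43.8, 65.6 and 40.6 CPM, and Klf9 rose by 1.19 (SE 0.21, adjusted p = 0.00594). That call was lost without Wt-Cre replicate 1 at 8 weeks (log2 fold change 1.10, adjusted p = 0.0548). Within Wt-Cre hearts Klf9 rose by 2.94 from 1 to 4 weeks (SE 0.18, adjusted p = 7.88e-10) and fell by 1.15 from 4 to 8 weeks (SE 0.17, adjusted p = 0.000346). The genotype effect on Klf9 differed between 4 weeks and 1 week (−2.89, SE 0.24, adjusted p = 2.01e-06) and between 8 weeks and 1 week (−2.11, SE 0.24, adjusted p = 2.85e-05). The difference between 8 and 4 weeks was 0.79 (SE 0.24, adjusted p = 0.133) in edgeR and passed in DESeq2 (0.82, adjusted p = 0.0493). The counts do not separate transcripts of the inserted copy from those of the endogenous gene.

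**Figure D1:**
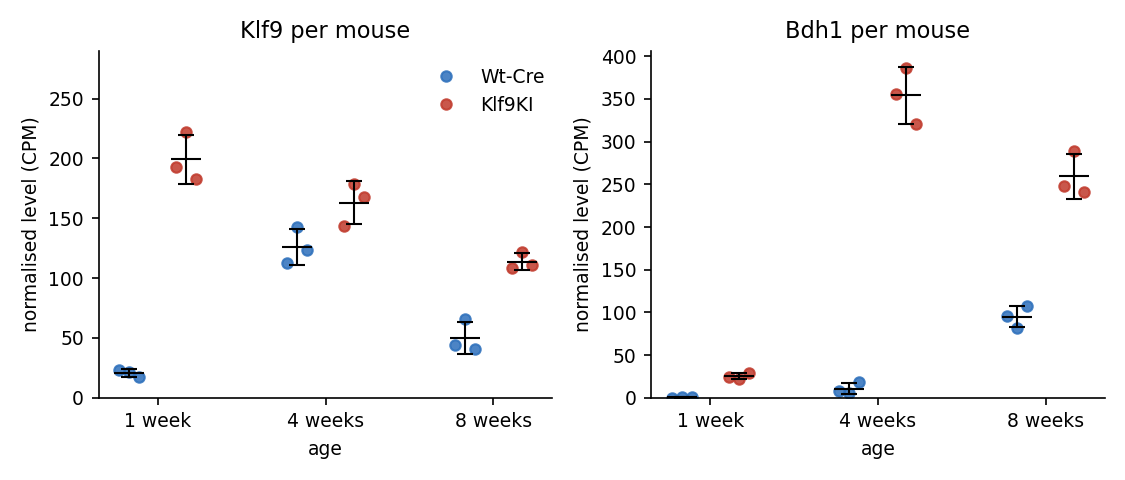
Klf9 and Bdh1 in each library, in CPM, with points for single hearts and black bars for the mean and SD of the 3 hearts of each group at 1, 4 and 8 weeks. Klf9 in Wt-Cre hearts went from 20.8 CPM at 1 week to 126 CPM at 4 weeks, near the 163 CPM of the Klf9KI hearts of that age.

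The comparison at 1 week asks which genes differed when Klf9 stood far above its neonatal level. Bdh1, the mitochondrial enzyme that interconverts the ketone bodies beta-hydroxybutyrate and acetoacetate, rose from 0.777 ± 0.472 to 25.3 ± 3.79 CPM (log2 fold change 5.03, SE 0.36, adjusted p = 4.53e-05, n = 3 per group). The folate enzyme Aldh1l1 rose by 3.08 on the log2 scale, the sodium-proton exchanger Slc9a3 by 2.50, the glutathione transferase Gstk1 by 1.75, the xylulose reductase Dcxr by 1.66 and the transaminase Kyat3 by 1.64. Among the genes that fell were Acta1, the skeletal muscle actin of the immature heart (14.3 ± 3.55 against 68.2 ± 19.9 CPM, log2 fold change −2.26, SE 0.25, adjusted p = 0.00442), and the perinatal myosin Myh8 (−2.18). The calls of Dcxr, Kyat3 and Myh8 were lost in 9, 8 and 8 of 17 alternatives, and with the Myl7 covariate, chosen after seeing the data, the log2 fold changes of Dcxr and Myh8 were 0.965 and −1.279. The vesicular glutamate transporter Slc17a7 fell by 2.64 and the microtubule-binding protein Mapt by 2.51. Also lower were the phosphorylase kinase subunit Phkg1 (−2.05), the chloride channel Clcn1 (−2.01), the amino acid transporter Slc36a2 (−1.87) and the mitochondrial alanine transaminase Gpt2 (−1.71).

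Across all genes at 1 week, edgeR called 266 of 15825, 103 of them higher and 163 lower in Klf9KI hearts. Sex was not balanced between these libraries. Klf9KI replicates 1 and 2 carried Xist, the non-coding RNA of the inactive X chromosome, at 710.1 and 607.3 CPM and no counts of the Y-linked Eif2s3y, while the other 4 hearts stood under 2 CPM of Xist. Only 1 Klf9KI library, replicate 3, thus matched the Wt-Cre hearts. All 18 libraries in 1 fit gave 47 genes at this age. With sex as a covariate 10 genes were called and without those 2 libraries 21, both chosen after seeing the data. In both fits the genotype effect rests on that 1 Klf9KI library, so sex and the loss of replicates were not separated. Klf9 (log2 fold change 3.14, adjusted p = 8.37e-07 with the covariate), Bdh1 (5.25, adjusted p = 0.000417), Gstk1 (1.81, adjusted p = 0.0108) and the leucine-breakdown enzyme Ivd (1.07, adjusted p = 0.0197) stayed past the threshold in both. The 45 called genes followed one by one at this age kept their direction in both fits, and 41 of them lost the call with the covariate and 39 without the 2 libraries. Some folds stayed near their main values, such as Acta1 at −2.32 with the covariate and −2.30 without the 2 libraries and Mapt at −2.52 and −2.505. Others moved, with Dbp at −0.647 and −0.632 and Ddit4l at −3.44 and −3.42, against −1.07 and −2.15 in the main fit. The count was also 78 without Klf9KI replicate 2, 112 without Klf9KI replicate 3, 140 without Wt-Cre replicate 1 and 91 without Wt-Cre replicate 3, all at 1 week.

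Several groups of metabolic genes stood higher at 1 week. Of 22 measured genes of branched-chain amino acid breakdown 5 rose and 1 fell over all genes tested, and 8 and 2 adjusted over the list alone. Ivd rose from 119 ± 5.31 to 239 ± 27.6 CPM (log2 fold change 1.01, SE 0.11, adjusted p = 0.00027), Pcca rose by 0.87 and Bckdhb by 0.84, and Acadsb was the member that fell (−0.72). The list stood higher than other genes (adjusted p = 9.56e-06, and adjusted p = 0.689 with an estimated correlation). Of 6 ketone body genes Bdh1 rose, with 4 higher adjusted over the list alone (adjusted p = 7.24e-09, and adjusted p = 0.112 with an estimated correlation). Of 36 nuclear genes of respiratory complex I 3 rose, Ndufs8 by 0.53, Ndufv3 by 0.51 and Ndufb9 by 0.47, and 10 adjusted over the list alone. The list median was 0.28 (adjusted p = 2.11e-11, and adjusted p = 0.743 with an estimated correlation). Among 41 genes of complexes II to V 1 rose, and 3 adjusted over the list alone (median 0.23, adjusted p = 1.08e-07, and adjusted p = 0.743 with an estimated correlation). Mitochondrial counts were 13.7 to 14.1% of the total in Klf9KI and 11.0 to 13.0% in Wt-Cre libraries at 1 week. Lists of mitochondrially encoded genes (adjusted p = 0.0355), cytosolic ribosomal proteins (adjusted p = 9.82e-05) and endothelial markers (adjusted p = 0.0383) also stood higher at this age. Matrix genes stood lower (median −0.21, adjusted p = 0.0212). None of these 4 lists passed with an estimated correlation (adjusted p = 0.743, 0.77, 0.743 and 0.798 in that order). The matrix call was lost without Klf9KI replicate 2 or 3 or Wt-Cre replicate 1 or 3 (adjusted p = 0.0763 to 0.316). The mitochondrially encoded call was lost without replicate 3 of either genotype (adjusted p = 0.287 and 0.175), and the endothelial call without Klf9KI replicate 3 or Wt-Cre replicate 2 or 3 (adjusted p = 0.0732 to 0.116).

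Other genes passed singly, most of them in lists that did not. The glucose transporter Slc2a1 rose from 11.5 ± 1.01 to 23.0 ± 4.84 CPM, the lipase Lpl by 0.60, the mitochondrial pyruvate carrier Mpc1 by 0.68 and the glutathione peroxidases Gpx1 and Gpx4 by 0.68 and 0.50. Acads, the short-chain acyl-CoA dehydrogenase of beta-oxidation, fell from 155 ± 7.67 to 74.8 ± 14.4 CPM (log2 fold change −1.05, SE 0.13, adjusted p = 0.000811). The pyruvate dehydrogenase kinase Pdk1 fell by 0.61, malic enzyme Me1 by 0.87 and the acyltransferase Agpat2 by 1.00. In the Krüppel-like family Klf15 rose from 8.27 ± 1.34 to 21.6 ± 0.834 CPM and Klf13 fell by 0.53. The clock outputs Dbp and Per3 fell by 1.07 and 0.63 (circadian list adjusted p = 0.0528). Of 27 ion channel genes 2 fell, Cacna1h by 0.92 and Kcnj5 by 0.58, and 5 adjusted over the list alone (list adjusted p = 0.000861, and adjusted p = 0.689 with an estimated correlation). The 10 atrial marker genes stood lower as a list (median −1.05, adjusted p = 0.000575, and adjusted p = 0.743 with an estimated correlation). Over all genes, 51 were called with the level of the atrial light chain Myl7 as a covariate, which was chosen after seeing the data. The natriuretic peptide Nppa was −0.95 (adjusted p = 0.642) and the slow myosin Myh7 0.61 (adjusted p = 0.397) at this age.

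The comparison at 4 weeks asks the same question at an age at which the difference in Klf9 was 0.37 on the log2 scale and passed only with the replicate block. Nppa, the atrial natriuretic peptide that ventricles make again under stress, rose from 59.1 ± 25.3 to 1779 ± 578 CPM (log2 fold change 4.91, SE 0.39, adjusted p = 0.000105, n = 3 per group). Bdh1 rose from 10.8 ± 6.79 to 354 ± 32.9 CPM (5.04, SE 0.41, adjusted p = 0.000171). The mitochondrial folate enzyme Mthfd2 rose from 2.93 ± 1.46 to 55.7 ± 4.62 CPM (4.25, SE 0.27, adjusted p = 6.35e-06). The largest rises were in the interferon-induced Apol9a (7.07) and Apol9b (6.39). Ces1d, a carboxylesterase that hydrolyses lipid esters, fell from 91.1 ± 17.9 to 2.09 ± 0.561 CPM (−5.44, SE 0.23, adjusted p = 4.41e-07). Slc36a2 fell from 32.5 ± 0.834 to 1.40 ± 0.186 CPM (−4.53), and Kcnd3, the pore of a transient outward potassium current, fell by 4.16 from 21.6 ± 2.09 CPM. The retinol acyltransferase Lrat fell by 5.16, Trim7 by 3.96 and Clcn1 by 3.78. In edgeR the test called 1945 of 14513 genes, 965 higher and 980 lower. The count was 873, 1109 and 1013 without Klf9KI replicate 1, 2 or 3 at 4 weeks.

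Of 17 fetal and cardiac stress genes 13 rose, and 14 adjusted over the list alone (median 1.81, adjusted p = 2.95e-24, and adjusted p = 0.0643 with an estimated correlation). The titin-binding Ankrd1 rose from 487 ± 168 to 5506 ± 643 CPM, Nppb from 118 ± 53.9 to 745 ± 28.1 CPM and Myh7 from 599 ± 235 to 2177 ± 183 CPM. Of 20 inflammatory and interferon-response genes, tested as 1 list, 14 rose over all genes tested and adjusted over the list alone (median 1.96, adjusted p = 3.35e-34, and adjusted p = 0.041 with an estimated correlation). Among them were Irf7 (12.5 ± 4.32 to 183 ± 11.5 CPM), Ifit1 (8.00 ± 1.70 to 108 ± 6.91 CPM) and Oasl2 (2.34). Of 27 genes of the ATF4 and mitochondrial stress response 17 rose, and 19 rose and 1 fell adjusted over the list alone (median 0.83, adjusted p = 2.53e-19, and adjusted p = 0.041 with an estimated correlation). They included the asparagine synthetase Asns (5.23 ± 0.255 to 45.4 ± 6.89 CPM), the serine-synthesis enzyme Phgdh (3.73) and the amino acid transporter Slc7a5 (2.50). Of 38 extracellular matrix genes 16 rose, and 26 adjusted over the list alone, with Ltbp2 at 3.44, Tgfb2 at 2.04 and Col8a1 at 1.99 (list median 0.86, adjusted p = 1.43e-15, and adjusted p = 0.495 with an estimated correlation).

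Lists of mitochondrial and lipid genes and of excitability stood lower at 4 weeks. Of 30 genes of fatty acid uptake and beta-oxidation 20 fell, and 26 adjusted over the list alone (median −0.84, adjusted p = 1.42e-17, and adjusted p = 0.173 with an estimated correlation). Acads fell from 135 ± 12.8 to 31.9 ± 2.37 CPM, Echs1 by 1.10, Cpt2 by 1.07 and Acaa2 by 0.94, whereas Cpt1b was −0.67 (adjusted p = 0.142). Of 29 ion channel genes 15 fell and 1 rose, and 18 and 1 adjusted over the list alone, with Hcn4 at −2.99, Kcnj3 at −2.59 and Hcn2 at −1.51 (list adjusted p = 2.9e-14, and adjusted p = 0.121 with an estimated correlation). Of 26 genes of triglyceride storage 9 fell and 2 rose, and 10 and 3 adjusted over the list alone, with Plin3 at −1.503 and Lpin1 at −1.505 (list adjusted p = 0.000635, and adjusted p = 0.121 with an estimated correlation). The insulin-responsive glucose transporter Slc2a4 fell from 361 ± 16.4 to 153 ± 16.6 CPM and Slc2a1 rose by 1.39. Of 19 clock genes 7 fell, and 10 adjusted over the list alone, including Hlf by 2.23 (list adjusted p = 0.00115, and adjusted p = 0.263 with an estimated correlation). Of 28 citric acid cycle genes 7 fell, and 12 adjusted over the list alone (adjusted p = 0.000365, and adjusted p = 0.568 with an estimated correlation), beside mitochondrial counts of 19.3 to 19.8% of the total in Klf9KI and 20.2 to 24.9% in Wt-Cre libraries. Respiratory chain lists were lower as well. Of 36 complex I genes 2 fell, and 0 adjusted over the list alone (median −0.24, adjusted p = 0.00445). Of 41 genes of complexes II to V 3 fell, and 2 adjusted over the list alone (median −0.28, adjusted p = 0.000244). Of 13 mitochondrially encoded genes 3 fell (median −0.29, adjusted p = 0.0484). Of 22 branched-chain amino acid genes 5 fell (list adjusted p = 0.00351). With an estimated correlation these 4 lists had an adjusted p of 0.632, 0.577, 0.578 and 0.568. The mitochondrially encoded call was lost without Klf9KI replicate 2 or 3 or Wt-Cre replicate 1 or 3 (adjusted p = 0.0602 to 0.167), and the complex I call without Wt-Cre replicate 3 (adjusted p = 0.167). The glycolysis list, with 3 of 25 higher and 5 lower, did not pass (adjusted p = 0.192). Nor did the list of biogenesis regulators (adjusted p = 0.305), of which 2 of 18 fell, Ppargc1a by 1.24 and Ppara by 1.12. These 2 calls were lost in 4 and 6 of 14 alternatives. Of 20 calcium-handling genes 7 fell, and 8 adjusted over the list alone, with Hrc at −1.30 and the calcium pump Atp2a2 at −0.88 (list adjusted p = 0.00424, and adjusted p = 0.568 with an estimated correlation). Macrophage markers stood higher beside the inflammatory and interferon genes, with 7 of 21 rising, and 10 higher and 1 lower adjusted over the list alone (median 0.55, adjusted p = 0.00351, and adjusted p = 0.568 with an estimated correlation).

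**Figure D2:**
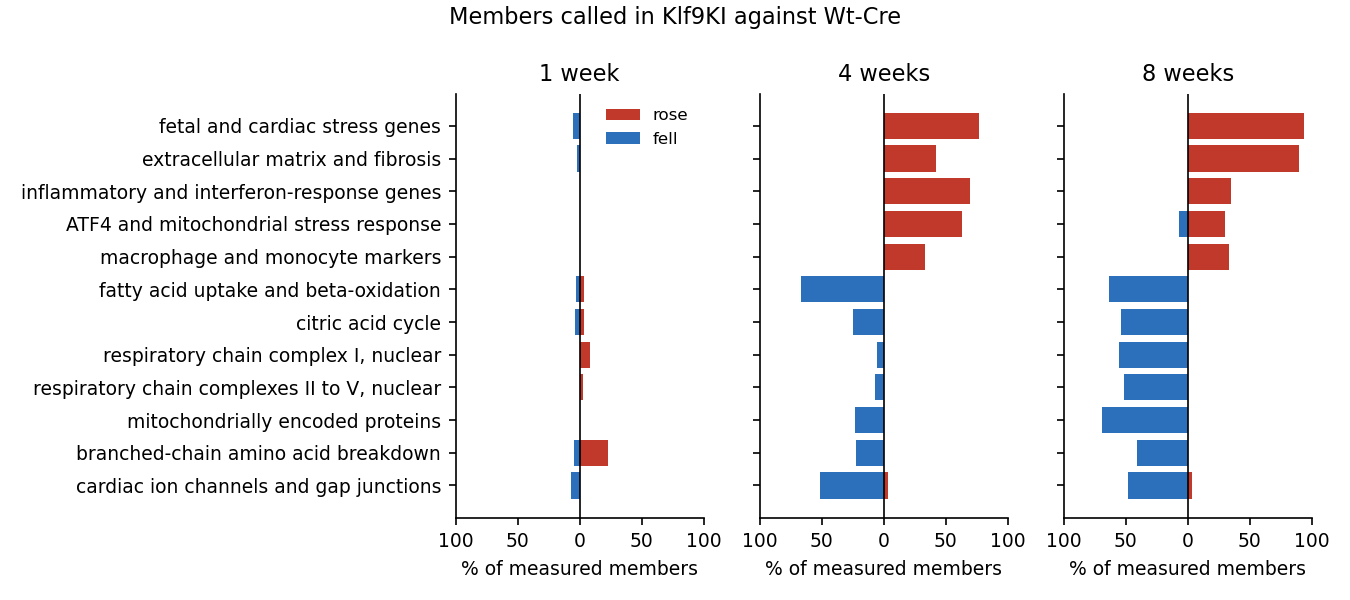
Share of the measured members of each gene list that rose (right) or fell (left) in Klf9KI against Wt-Cre hearts, in percent, at 1, 4 and 8 weeks (n = 3 hearts per group, edgeR). Of 40 extracellular matrix genes 36 rose at 8 weeks, against 16 of 38 at 4 weeks.

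At 8 weeks the comparison asks which differences were present at the last age collected. Matrix genes were among the large rises. Comp, the cartilage oligomeric matrix protein, rose from 1.87 ± 0.895 to 115 ± 48.1 CPM (log2 fold change 5.95, SE 0.46, adjusted p = 7.2e-05, n = 3 per group). Ltbp2 rose from 4.04 ± 2.28 to 146 ± 55.5 CPM (5.18), and Postn, made by activated fibroblasts, from 34.0 ± 8.40 to 582 ± 228 CPM (4.10, SE 0.33, adjusted p = 9.31e-05). Myh7, the slow myosin of the fetal ventricle, rose from 231 ± 58.2 to 3740 ± 2221 CPM (4.02, SE 0.46, adjusted p = 0.000548). Nppa rose from 107 ± 85.9 to 1848 ± 428 CPM (4.11, SE 0.51, adjusted p = 0.0008). Sprr1a, a stress protein of cardiomyocytes, had no counts in Wt-Cre hearts and stood at 7.78 CPM in Klf9KI hearts, at least 98.6-fold higher against a floor of 3 counts over the group. Ces1d fell from 121 ± 4.56 to 0.831 ± 0.668 CPM (−7.09, SE 0.49, adjusted p = 5.33e-05), and Slc36a2 from 43.4 ± 5.81 to 0.699 ± 0.441 CPM (−5.99). The sodium channel subunit Scn4b fell from 33.4 ± 4.01 to 0.846 ± 0.611 CPM (−5.36). Bdh1 rose by 1.44 (SE 0.19, adjusted p = 0.0011), from 95.2 ± 12.8 to 259 ± 26.5 CPM. edgeR called 1518 of 14483 genes, 719 higher and 799 lower. Klf9KI replicate 2 stood apart in its group, with a chi-square per gene of 84.7 and 116 against replicates 1 and 3, where no other pair of libraries within a group at any age exceeded 41.7. Its Myh7 level was 5867 CPM, against 3918 and 1435 CPM in the others. The count was 3278 when all 18 libraries were fitted together, and 769 without Klf9KI replicate 1 and 543, 518 and 695 without Wt-Cre replicate 1, 2 or 3 at 8 weeks.

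Of 40 extracellular matrix genes 36 rose, and 38 adjusted over the list alone (median 2.34, adjusted p = 1.77e-49, and adjusted p = 0.121 with an estimated correlation). Besides Comp and Postn they included Tgfb2 (2.96), and Mfap5 (2.29) and Pi16 (1.72) rose among the fibroblast markers. Of 11 fibroblast markers 2 rose, and 5 rose and 1 fell adjusted over the list alone (median 0.53, adjusted p = 0.00135, and adjusted p = 0.27 with an estimated correlation). Of 17 fetal and stress genes 16 rose, and all 17 adjusted over the list alone (median 2.03, adjusted p = 1.1e-27, and adjusted p = 0.121 with an estimated correlation). Ankrd1 went from 1390 ± 76.0 to 8017 ± 327 CPM, and the nicotinamide riboside kinase Nmrk2 rose by 2.46 and the costamere protein Xirp2 by 2.41. Of 21 macrophage markers 7 rose, including Cx3cr1 by 2.07, and 11 rose and 1 fell adjusted over the list alone (median 0.72, adjusted p = 0.000133, and adjusted p = 0.178 with an estimated correlation). The inflammatory and interferon list had 7 of 20 higher, and 9 higher and 1 lower adjusted over the list alone (Irf7 12.8 ± 1.84 to 60.2 ± 18.5 CPM, list adjusted p = 3.02e-06, and adjusted p = 0.145 with an estimated correlation). Of 27 ATF4 genes 8 rose and 2 fell, and 11 and 3 adjusted over the list alone, with Mthfd2 at 2.101 and Asns at 1.98 (list adjusted p = 0.000183, and adjusted p = 0.145 with an estimated correlation).

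Genes of the respiratory chain, the citric acid cycle and fatty acid oxidation fell at 8 weeks, while lists of mitochondrial dynamics (adjusted p = 0.0977) and of biogenesis regulators (adjusted p = 0.0684) did not pass. Still, 2 of 18 biogenesis regulators fell singly, Ppargc1a by 0.81 and Rxrg by 1.14. The call of Ppargc1a was lost in 5 of 14 alternatives. Of 36 nuclear complex I genes 20 fell, and 31 adjusted over the list alone (median −0.86, adjusted p = 7.62e-16, and adjusted p = 0.277 with an estimated correlation), among them Ndufs4 (−1.31) and Ndufb4 (−1.23). Of 41 genes of complexes II to V 21 fell, and 37 adjusted over the list alone (median −0.87, adjusted p = 1.35e-17, and adjusted p = 0.271 with an estimated correlation). The heart-type subunit Cox7a1 fell from 515 ± 67.2 to 121 ± 42.9 CPM. Of 13 mitochondrially encoded genes 9 fell, including mt-Co3 by 1.24 (list median −0.80, adjusted p = 1.32e-06, and adjusted p = 0.145 with an estimated correlation). Mitochondrial counts were 18.6 to 20.9% of the total in Klf9KI and 27.7 to 29.7% in Wt-Cre libraries. Of 28 citric acid cycle genes 15 fell, and 22 adjusted over the list alone, with Sucla2 at −1.17 (list adjusted p = 3.43e-11, and adjusted p = 0.178 with an estimated correlation). Of 30 fatty acid genes 19 fell, and 22 adjusted over the list alone (median −1.11, adjusted p = 2.72e-18, and adjusted p = 0.121 with an estimated correlation). The thiolase Acaa2 went from 1123 ± 148 to 286 ± 37.8 CPM, Acads fell by 1.505 and Hadh by 1.32. Of 22 branched-chain amino acid genes 9 fell, and 14 adjusted over the list alone, with Hsd17b10 at −1.47 (list adjusted p = 3.68e-09, and adjusted p = 0.125 with an estimated correlation). Of 29 ion channel genes 14 fell and 1 rose, and 14 and 2 adjusted over the list alone, with Kcnj3 at −4.39 and Hcn2 at −2.40 (list adjusted p = 6.32e-11, and adjusted p = 0.108 with an estimated correlation). Slc2a4 fell from 394 ± 10.3 to 136 ± 6.11 CPM and the calcium-binding Hrc fell by 2.097. Over all lists camera called 10 of 37 at 1 week, 19 of 37 at 4 weeks and 20 of 36 at 8 weeks. With an estimated correlation it called 0, 2 and 0, with 1, 7 and 10 under 0.05 before adjustment. The 1-week count was 17 without Klf9KI replicate 1 and 18 without Wt-Cre replicate 2 at that age.

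**Figure D3:**
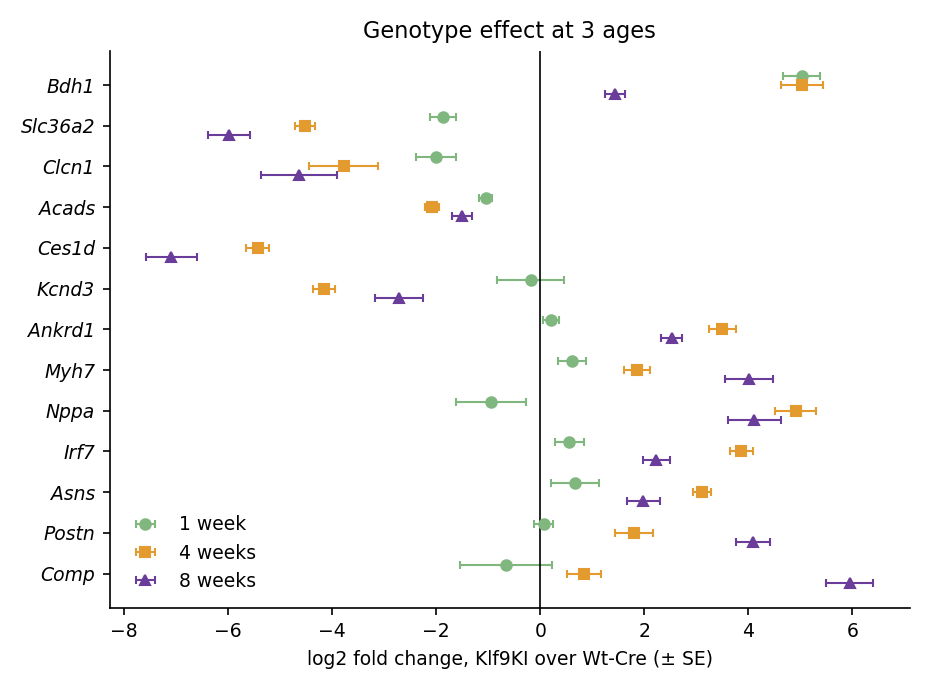
Log2 fold change of named genes in Klf9KI against Wt-Cre hearts, with bars for 1 standard error of the edgeR fit, at 1, 4 and 8 weeks (n = 3 hearts per group). Bdh1 stood at 5.03, 5.04 and 1.44 in order of age, and Acads at −1.05, −2.08 and −1.505.

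Did the genotype effect itself differ between ages? Between 4 weeks and 1 week it differed for 192 of 16660 genes, 114 with a higher and 78 with a lower effect at 4 weeks. The effect on Nppa was higher by 5.86 (adjusted p = 0.00354) and that on the interferon-induced Apol9a by 7.26 (adjusted p = 0.00803). At 4 weeks Apol9a stood at 0.088 CPM in Wt-Cre and 13.2 CPM in Klf9KI hearts, so the size of its difference is uncertain. The list of 9 atrial markers, which holds Nppa, moved up in the added list tests (median 2.15, adjusted p = 1.74e-06, and adjusted p = 0.0843 with an estimated correlation). Only 1 member, Nppa itself, passed singly. The muscle ribosomal protein Rpl3l, which Wt-Cre hearts raised from 9.56 to 225 CPM and Klf9KI hearts from 9.56 to 24.4 CPM, had a log2 difference of −3.199 (SE 0.29, adjusted p = 2.28e-06). In list tests chosen after seeing the data the effect was higher at 4 weeks for inflammatory and interferon genes (10 of 22 higher, adjusted p = 7.47e-24, and adjusted p = 0.000378 with an estimated correlation). It was lower for fatty acid genes (4 lower, adjusted p = 1.27e-19, and adjusted p = 0.029 with an estimated correlation). Sex as a covariate, which rests the 1-week effect on 1 Klf9KI library, left 95 genes, DESeq2 called 399, and the count was 115 without Wt-Cre replicate 3 at 1 week, 106 without Klf9KI replicate 1 at 4 weeks and 298 without Klf9KI replicate 2 at 8 weeks.

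From 4 to 8 weeks the effect differed for 80 genes, 26 with a higher and 54 with a lower effect at 8 weeks. The effect on Bdh1 was lower by 3.62 (SE 0.44, adjusted p = 0.00277), and the effects on the matrix genes Comp and Postn were higher by 5.08 (adjusted p = 0.0436) and 2.27 (adjusted p = 0.0388). The calls of Comp and Postn were lost in 15 and 14 of 24 alternatives, while that of Bdh1 stayed in all 24. In the added list tests inflammatory and interferon genes had a lower effect at 8 than at 4 weeks (4 of 22 lower, adjusted p = 1.79e-08, and adjusted p = 0.0405 with an estimated correlation). The count of 80 moved with many settings. DESeq2 called 416 genes, and the edgeR count was 28, 18 and 32 without Klf9KI replicate 1, 2 or 3 at 4 weeks and 33 without Wt-Cre replicate 2 at 4 weeks. At 8 weeks it was 51, 131 and 491 without Klf9KI replicate 1, 2 or 3 and 29 and 21 without Wt-Cre replicate 1 or 2.

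Across the whole span, 8 weeks against 1 week, the effect differed for 1574 genes, 653 with a higher and 921 with a lower effect at 8 weeks. The effect was higher by 6.59 for Comp and by 5.74 for Ltbp2, and lower by 5.60 for Frmpd3 and by 5.12 for the water channel Aqp4. Frmpd3 and Aqp4 stood at 0.0536 and 0.35 CPM in Klf9KI hearts at 8 weeks, so the size of these falls is uncertain. In the list tests, also chosen after seeing the data, 36 of 40 matrix genes had a higher effect (adjusted p = 4.62e-39, and adjusted p = 0.0423 with an estimated correlation). Of 36 complex I genes 30 had a lower one (adjusted p = 1.05e-30, and adjusted p = 0.0696 with an estimated correlation). Sex as a covariate, with the same limit, left 790 genes, and the count was 942 without Klf9KI replicate 2 at 1 week, 974 without Wt-Cre replicate 3 at 1 week and 2414 without Klf9KI replicate 3 at 8 weeks.

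Wt-Cre hearts alone gave the changes with age against which the genotypes were read, although age could not be told apart from a sequencing batch that followed age. The list tests on these changes were added after seeing the data. From 1 to 4 weeks 5828 genes changed, 2895 up and 2933 down. Of 34 cell cycle genes 31 fell (median −3.04, adjusted p = 1.03e-23, and adjusted p = 0.0857 with an estimated correlation). Of 40 matrix genes 31 fell (adjusted p = 2.66e-12, and adjusted p = 0.192 with an estimated correlation). Of 28 citric acid cycle genes 25 rose (adjusted p = 5.86e-11, and adjusted p = 0.148 with an estimated correlation). Of 20 glucocorticoid-responsive genes 17 rose (list adjusted p = 3.17e-08, and adjusted p = 0.0857 with an estimated correlation). From 4 to 8 weeks 3180 genes changed, 1833 up and 1347 down. Of 45 cytosolic ribosomal protein genes 43 fell from 1 to 4 weeks (median −0.98, adjusted p = 3.05e-14, and adjusted p = 0.277 with an estimated correlation). From 4 to 8 weeks 44 of them rose (median 1.18, adjusted p = 1.01e-34, and adjusted p = 0.279 with an estimated correlation). The count of 3180 was 2097 and 2004 without Wt-Cre replicate 1 or 2 at 4 weeks and 2040 without Wt-Cre replicate 1 at 8 weeks.

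Genes called at more than one age mostly went the same way. At 1 and 4 weeks 39 genes were higher both times, where 6.61 would be shared by chance, and 104 lower, where 10.5 would be (14144 genes tested at both ages, Fisher's exact test, two-sided, p = 9.74e-21 and p = 2.29e-84). At 4 and 8 weeks 306 were higher and 411 lower both times, against 47.5 and 54.5 by chance. At 1 and 8 weeks the counts were 18 and 56, against 5.02 and 8.75. Opposite ways went 5 genes at 1 and 4 weeks (16.99 by chance), 4 at 4 and 8 weeks (102) and 12 at 1 and 8 weeks (13.4). The 12 became 22 without Klf9KI replicate 1 (11.7 by chance) and 20 without Wt-Cre replicate 2 (11.4 by chance) at 1 week. Without Klf9KI replicate 2 or 3 at 1 week the number was 3 (3.93 and 5.54 by chance). With DESeq2 calls 48 went opposite ways at 1 and 8 weeks (36.5 by chance) beside 118 the same way. At all 3 ages 16 genes were higher, among them Bdh1, Slc9a3, Aldh1l1 and Slc2a1, and 50 lower, among them Acads, Acadsb, Slc36a2, Clcn1, Phkg1 and Gpt2. Without the 2 libraries that carried Xist, which leaves 1 Klf9KI library at 1 week, 10 genes were shared by 1 and 4 weeks and 6 by 1 and 8 weeks. The 143 genes shared in 1 direction by 1 and 4 weeks numbered 54, 65, 74 and 62 without Klf9KI replicate 2 or 3 or Wt-Cre replicate 1 or 3 at 1 week and 93 without Klf9KI replicate 1 at 4 weeks. The 717 shared by 4 and 8 weeks numbered 452 without Klf9KI replicate 1 at 4 weeks, and 445, 366, 347 and 414 without Klf9KI replicate 1 or Wt-Cre replicate 1, 2 or 3 at 8 weeks. The 74 shared by 1 and 8 weeks numbered 40, 37, 44 and 38 without Klf9KI replicate 2 or 3 or Wt-Cre replicate 1 or 3 at 1 week. They numbered 43, 42 and 49 without Wt-Cre replicate 1, 2 or 3 at 8 weeks.

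The chromatin data ask where Klf9 sits in the adult heart and whether pressure overload moves it. The authors' table held 5238 regions on mm10, and 4228 of them (80.7%) overlapped a CpG island and 4114 (78.5%) lay within 1 kb of a gene start. Regions were called in sham at 4645 places and in TAC at 4073, and 3480 (66.4%, exact binomial 95% confidence interval 65.1 to 67.7%) were called in both. That interval treats regions as independent and measures no spread between hearts. The strongest sham values lay at the starts of Sssca1 (chromosome 19, 5731504 to 5732134, sham 115, TAC 107), Hist1h3g (chromosome 13, 23535028 to 23535517, 115 and 117) and Armc7 (chromosome 11, 115475320 to 115476089, 114 and 110). Dbp, a clock output gene, held one of the 10 highest (chromosome 7, 45705744 to 45706292, 97.7 and 86.8). Klf9 had 5 regions at its own locus, with 20.7 to 32.1 in sham and 16.4 to 28.4 in TAC. The first lay at chromosome 19, 23140688 to 23141167 (32.1 and 19.8), and the last, at 23144079 to 23144483, was higher in TAC (25.2 and 28.4). Of all regions 181 (3.46%) differed at least 2-fold between conditions, 56 higher in TAC and 125 higher in sham. With values scaled to equal medians 80 were higher in TAC and 93 in sham. The values of the conditions had a rank correlation of 0.684 across regions, which are not independent replicates. With 1 library per condition no test between sham and TAC was run.

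Genes with a Klf9 region were then compared with the RNA calls, the question being whether genes at bound sites went up or down in Klf9KI hearts. Regions were more frequent among genes called lower, and less frequent among genes called higher, than among genes not called. At 1 week 93 of 160 genes called lower (58.1%) had a region in sham hearts, against 35.8% of genes not called (odds ratio 2.49, adjusted p = 2.5e-08, Fisher's exact test, two-sided). Regions lay at 27 of 102 genes called higher (26.5%, odds ratio 0.645, adjusted p = 0.0495). At 4 weeks regions lay at 460 of 936 genes called lower (49.1%, odds ratio 1.57, adjusted p = 1.6e-10) and at 215 of 958 called higher (22.4%, odds ratio 0.469, adjusted p = 7.45e-23). At 8 weeks they lay at 321 of 761 called lower (42.2%, odds ratio 1.19, adjusted p = 0.0281) and 190 of 715 called higher (26.6%, odds ratio 0.590, adjusted p = 7.49e-10). Genes that fell with a region at their start included Acads (chromosome 5, 115118980 to 115119682, sham 73.5), Slc36a2 (chromosome 11, 55184949 to 55185222, sham 23.6) and, at 4 and 8 weeks, Cpt2 (chromosome 4, 107923395 to 107923872, sham 45.5). Genes that rose with a region at or near their start included Slc2a1 at all 3 ages (chromosome 4, 119108555 to 119108906, sham 28.6) and Dcxr at 1 week (chromosome 11, 120727255 to 120727545, sham 33.7). At 4 and 8 weeks they included Slc7a5 (chromosome 8, 121907639 to 121908087, sham 16.9) and Irf7 (chromosome 7, 141265942 to 141266245, sham 22.5). Bdh1, Nppa and Ppargc1a had none.

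The hearts for chromatin were older than those for RNA, and the labels name no knock-in for them. A background matched on expression and gene length turned the 8-week odds ratio for lower genes to 0.914 (adjusted p = 0.261). With DESeq2 calls and genes without an adjusted p kept in the background, chosen after seeing the data, the ratio for higher genes turned to 1.31 at 1 week (adjusted p = 0.0556) and 1.39 at 8 weeks (adjusted p = 1.94e-05). Such genes could not be called. Keeping them cut the share with a region among genes not called from 36.4 to 22.9% at 8 weeks. The ratio for lower genes rose too, from 1.255 to 2.41 at that age. This background thus cannot show that higher genes hold regions more often. The 8-week ratio for lower genes missed the threshold without Klf9KI replicate 1 (1.16) and without Wt-Cre replicate 1 (1.15), 2 (1.25) or 3 (1.24) at 8 weeks. At 1 week the ratio for higher genes missed it without Klf9KI replicate 1 (0.704) or 2 (0.584) and without Wt-Cre replicate 1 (0.606) or 3 (0.483). The ratio for lower genes at 1 week missed it without the 2 libraries that carried Xist, which leaves 1 Klf9KI library (2.60, adjusted p = 0.238). That ratio was 1.47 without Klf9KI replicate 1 (adjusted p = 0.0411), and the ratio for higher genes was 0.351 without Klf9KI replicate 3 (adjusted p = 0.0242), both at 1 week.

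**Figure D4:**
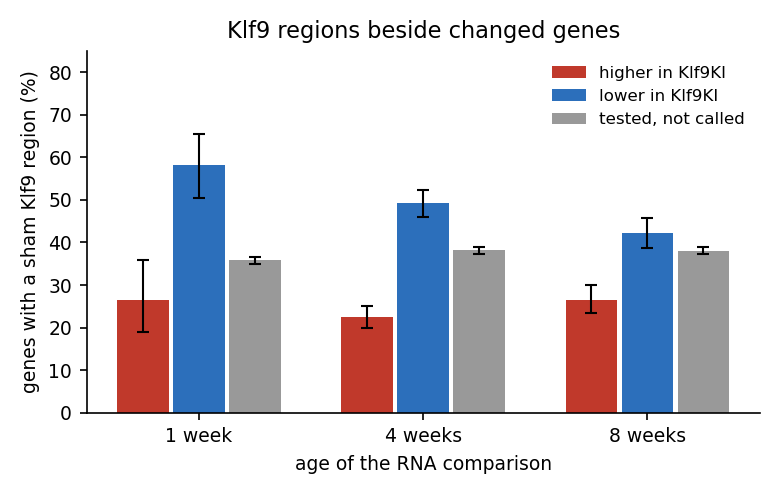
Percentage of genes with a Klf9 region in sham hearts among genes called lower, not called and called higher in Klf9KI hearts at 1, 4 and 8 weeks, with Wilson 95% confidence intervals. The share among genes called lower went from 58.1% at 1 week to 49.1% at 4 weeks and 42.2% at 8 weeks.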

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

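The tests of library scaling, of Klf9 in the Wt-Cre library, of mixed RNA, of another allele, of macrophages and of single libraries were chosen after the results were seen. Counts were also set against those of other splits of the same libraries. Splits that mix the genotypes put the genotype effect into the spread within groups, so they leave few calls by construction. They therefore cannot decide whether chance gave a count.

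The genotype effect differed between ages in the test of that difference. Between 4 weeks and 1 week 192 genes differed. Of 100 splits 1, the real one, gave as many and the highest other gave 33. Between 8 and 4 weeks 80 genes differed, and chance could not be excluded, since 11 of 100 splits gave as many and the highest gave 1414. The 10 other splits that reached 80 all kept the genotype groups of 1 age together and so carried the genotype effect of that age. The highest split without such a group gave 1. Between 8 weeks and 1 week 1574 genes differed. Of 100 splits 1, the real one, gave as many and the highest other gave 1120. Splits that mixed the genotypes at both ages gave at most 1 gene between 4 weeks and 1 week. Between 8 weeks and 1 week such splits gave at most 3. Chance was thus not excluded for 192 or 1574 genes.

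At 4 weeks the effect exceeded that at 1 week by 7.26 for Apol9a, 5.86 for Nppa, 5.15 for Plcxd2, 4.22 for the chemokine Cxcl10 and 4.00 for Tenm4 on the log2 scale. It was lower at 4 weeks, with a log2 difference of −3.945 for Kcnd3, −3.199 for Rpl3l, −2.89 for Klf9, −2.66 for Slc36a2 and −2.66 for the smooth muscle actin Acta2. At 8 weeks the effect exceeded that at 4 weeks by 5.08 for Comp, 2.44 for Myot, 2.375 for Ddah1, 2.27 for Postn and 2.08 for Nkd2. It was lower at 8 weeks, with −3.62 for Bdh1, −2.95 for Aqp4, −2.83 for Cxcl9, −2.80 for E330017L17Rik and −2.75 for Col6a6. Against 1 week the effect at 8 weeks was higher by 6.74 for the endothelin Edn3, 6.59 for Comp, 5.74 for Ltbp2 and 5.465 for Fgf6. It was lower with −6.74 for Ctla4, −6.355 for the pseudogene Gm13339, −5.60 for Frmpd3 and −5.12 for Aqp4. Cacng6 had no counts in Klf9KI hearts at 8 weeks, at least 24.7-fold lower there, and its effect differed from that at 1 week (adjusted p = 0.00325). Several of the differences above rest on a group mean under 1 CPM, so their size is uncertain. Klf9KI hearts at 1 week had 0.0174 CPM of Edn3 and 0.162 of Fgf6, and Wt-Cre hearts 0.0678 of Ctla4. At 8 weeks Klf9KI hearts had 0.0536 CPM of Frmpd3 and 0.35 of Aqp4. At 4 weeks Wt-Cre hearts had 0.088 CPM of Apol9a.

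The first pattern followed up is the small Klf9 difference at 4 weeks, 163 against 126 CPM, at an age with 1945 called genes. Library scaling was argued against, since the log2 difference between 4 weeks and 1 week stayed at −2.892 or lower under each other scaling, with an upper confidence bound of −2.41. Genotypes mixed up among the 4-week mice were argued against as well, since 73 genes called the same way at 1 and 8 weeks had a median ratio of their 4-week fold change to that of the other ages of 1.227 (quartiles 0.99 to 1.53). A glucocorticoid state of the control mice that differs between ages may account for part of the pattern, since glucocorticoid-responsive genes rose as a list in Wt-Cre hearts from 1 to 4 weeks (adjusted p = 3.17e-08, and adjusted p = 0.0857 with an estimated correlation). From 4 to 8 weeks, when Klf9 fell by 1.15 in Wt-Cre hearts, the list did not move (median −0.088, adjusted p = 0.925). With 5828 genes changing from 1 to 4 weeks, the list cannot tell a glucocorticoid state from other changes with age. Transcripts of the knock-in and the endogenous copy were not separable, and normal maturation of Klf9 expression stays open as untested.

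The second pattern is Gt(ROSA)26Sor, a transcript of the Rosa26 locus that many knock-in alleles use, at 174.9 CPM in Wt-Cre replicate 2 at 1 week, where the other Wt-Cre hearts had 11.6 and 9.76 CPM and the Klf9KI hearts 118.6 to 133.8 CPM. A mislabelled Klf9KI library was argued against by Klf9 itself, at 21.9 CPM where the lowest Klf9KI heart had 182.8 CPM. Over 226 genes called without it, its median place between the Wt-Cre (0) and Klf9KI (1) means was 0.266 (quartiles 0.017 to 0.524), so the bound set in advance, an upper quartile under 0.5, was narrowly missed. Klf9KI RNA mixed into the library was argued against, since the place of its Klf9 level was 0.0096 while that of Gt(ROSA)26Sor was 1.445. Another allele at the locus in this mouse could not be told apart from other causes, since the 174.9 CPM come from a table with no feature for an inserted cassette, and the labels do not place the knock-in. At 4 weeks the transcript stood at 52.2 to 55.3 CPM in Klf9KI and 7.27 to 10.8 CPM in Wt-Cre hearts. At 8 weeks it stood at 24.9 to 60.0 CPM in Klf9KI and 5.48 to 7.595 CPM in Wt-Cre hearts.

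The third pattern is the rise of the list of inflammatory and interferon-response genes at 4 weeks, with a median of 1.96 on the log2 scale. More macrophages alone were argued against, since their markers had a median of 0.552 (quartiles 0.160 to 0.902). A single library was argued against, since the highest adjusted p of the list without each of the 6 libraries was 7.09e-29. An effect that differs between ages is consistent with the list tests of that difference, the weaker of which had an adjusted p of 1.79e-08 (0.0405 with an estimated correlation). Infection or housing of the mice at this age was not recorded in the labels and stays open as untested.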

How the results depend on the processing

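Sex as a covariate, the Myl7 covariate, leaving out the libraries that carried Xist, leaving out mitochondrial genes and the wider DESeq2 background were chosen after the data were seen. Of 112 comparisons of a main result with an alternative other than a left-out library, 78 kept their direction and size, 27 moved by over 1.5 times, 4 missed the threshold and 3 reversed. Of 198 with 1 library left out 142 kept, 48 moved and 8 missed the threshold. For single genes and lists, called or not, 1873 of 2190 comparisons kept their direction and side of the threshold without 1 library, 316 lost a call and 1 reversed. In other alternatives 1901 of 2153 kept them, 250 lost a call and 2 gained one. Of the called genes followed one by one, 26 of 45 at 1 week, 18 of 84 at 4 weeks and 25 of 81 at 8 weeks lost their call in at least 1 fit without a library. For differences between ages 3 of 10 did so between 4 weeks and 1 week, 8 of 10 between 8 and 4 weeks and 0 of 11 between 8 weeks and 1 week. With 3 hearts per group and 12086856 to 32855383 counts per library, changes under 2-fold were often missed in simulated data. Changes of 2-fold were recovered in only 28.4% at 8 weeks and in 4.48 to 10.45% for differences between ages. For those differences 4-fold changes were recovered in 54.55 to 63.64%. For each value that moved below, the cause was not tested, except that a fold limit or fewer regions leave fewer calls by construction. Leaving out 1 library moved counts both ways, at 4 weeks from 1945 genes to between 873 and 2654.

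At 1 week (266 genes) DESeq2 called 530, no filter gave 672, all 18 libraries in 1 fit 47, sex as a covariate 10, leaving out the 2 libraries that carried Xist 21, the Myl7 covariate 51 and the 2-fold limit 75. Both fits for sex rest the 1-week effect on 1 Klf9KI library. At 4 weeks (1945) the 2-fold limit left 876, and at 8 weeks (1518) all 18 libraries in 1 fit gave 3278. Between 4 weeks and 1 week (192) DESeq2 called 399 and the sex covariate left 95. Between 8 and 4 weeks (80) DESeq2 called 416, and between 8 weeks and 1 week (1574) the sex covariate left 790. Camera called 10, 19 and 20 lists at 1, 4 and 8 weeks with the preset correlation and 0, 2 and 0 with an estimated one (1, 7 and 10 before adjustment), and fry called 1, 13 and 19.

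For regions and higher genes at 1 week (0.645) the odds ratio was 0.663 within 1 kb of a start (adjusted p = 0.112), 0.998 for the upper part of regions and 1.31 with the wider DESeq2 background (adjusted p = 0.0556). At 8 weeks the ratio for higher genes was 0.723 with DESeq2 calls (adjusted p = 1.463e-05). With the same calls, keeping genes without an adjusted p in the background reversed it to 1.39 (adjusted p = 1.94e-05). Those genes could not be called, and keeping them cut the share with a region among genes not called from 36.4 to 22.9%. For lower genes the ratio was 2.60 at 1 week without the libraries that carried Xist (adjusted p = 0.238), and at 8 weeks 1.155 within 1 kb (adjusted p = 0.0961) and 0.914 against the matched background (adjusted p = 0.261). Between sham and TAC the upper part of regions had 89.4% in both and 37 differing, and 970 differed at 1.5-fold. Shared calls at 1 and 4 weeks (143) numbered 242 in DESeq2, 37 at 2-fold and 10 without the libraries that carried Xist. At 4 and 8 weeks (717) they numbered 367 at 2-fold, and at 1 and 8 weeks (74) 118, 35 and 6.

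With 1 library left out in turn, the counts ran from 78 to 238 at 1 week, 873 to 2654 at 4 weeks and 518 to 2102 at 8 weeks. Differences between ages ran from 106 to 298, 18 to 491 and 942 to 2414 in the order above, and Wt-Cre ages from 4407 to 6586 and 2004 to 4073. The libraries that moved them by over 1.5 times are named with their values beside each count in the report. Lists ran from 11 to 18, 17 to 21 and 19 to 24, with 17 at 1 week without Klf9KI replicate 1 and 18 without Wt-Cre replicate 2. Odds ratios for higher genes ran from 0.351 to 0.704, 0.410 to 0.626 and 0.445 to 0.773 in order of age, and for lower genes from 1.47 to 3.21, 1.215 to 1.69 and 1.145 to 1.26. Shared calls ran from 54 to 171, 347 to 856 and 37 to 90. The ribosomal protein list at 8 weeks (adjusted p = 0.00909, lower, and adjusted p = 0.735 with an estimated correlation) turned direction without Klf9KI replicate 2 (adjusted p = 0.575), and was lowest without Klf9KI replicate 3 (adjusted p = 3.41e-06).

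The libraries share a replicate number within each age and nothing else ties them. Correlations of same-number pairs were 0.079, 0.097 and −0.118 at 1 week, 0.112, 0.029 and 0.232 at 4 weeks and 0.063, 0.101 and 0.144 at 8 weeks. Each library correlated best with its own number at 8 weeks, a hint from the data, and not at 1 or 4 weeks. A block on the number gave 189, 2566 and 1890 genes, and Klf9 passed with it at 4 weeks (0.37, adjusted p = 0.0311). The planned pseudocounts applied to normalised values alone and were not run.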

Other observations

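Beyond the groups described, Klf9KI hearts at 4 weeks showed changes in growth and stress genes. Of 34 cell cycle genes 7 rose and 1 fell, and 8 and 1 adjusted over the list alone, with Ccnb1 at 3.38 and the replication helicase Mcm7 at 1.26 (list adjusted p = 0.000332, and adjusted p = 0.568 with an estimated correlation). Of 20 apoptosis genes 4 rose, including Tnfrsf12a by 1.98 and the anti-apoptotic Bcl2 by 2.19 (list adjusted p = 0.00567, and adjusted p = 0.29 with an estimated correlation). The glucocorticoid list stood lower, with 3 of 19 falling (median −0.32, adjusted p = 0.0272, and adjusted p = 0.577 with an estimated correlation), a call lost without Klf9KI replicate 1 (adjusted p = 0.0822) and without Wt-Cre replicate 2 (0.0538) or 3 (0.232) at 4 weeks. Smooth muscle Acta2 fell from 662 ± 367 to 90.3 ± 20.5 CPM, while the smooth muscle list did not pass (adjusted p = 0.79). Of 6 skeletal muscle markers 2 fell, and 4 adjusted over the list alone (list median −1.356, adjusted p = 0.00783, and adjusted p = 0.568 with an estimated correlation). That list call was lost without Wt-Cre replicate 2 at 4 weeks (adjusted p = 0.123). Of 27 antioxidant genes 8 rose and 4 fell, among them Gpx1 by 0.97 and the haem oxygenase Hmox1 by 1.25 (list adjusted p = 0.137).

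At 8 weeks 5 of 18 immediate early genes rose, and 8 adjusted over the list alone, with Egr2 at 3.35 and Junb at 1.29 (list adjusted p = 0.000108, and adjusted p = 0.367 with an estimated correlation). Of 34 cell cycle genes 5 rose and 1 fell, and 10 and 1 adjusted over the list alone, including Top2a by 2.55 and Mki67 by 1.84 (list adjusted p = 7.97e-05, and adjusted p = 0.301 with an estimated correlation). Of 25 glycolysis genes 3 rose and 7 fell, with the platelet-type phosphofructokinase Pfkp at 1.26 (list adjusted p = 0.0272, and adjusted p = 0.445 with an estimated correlation), a call lost without Klf9KI replicate 3 (0.098) and without Wt-Cre replicate 1 (0.0629) at 8 weeks. Of 27 antioxidant genes 3 rose and 7 fell, Gpx3 by 2.06 and Nqo1 by 1.21 going up and Prdx5 by 1.10 going down (list adjusted p = 0.884). The list of 14 endothelial markers stood higher at 1 week (adjusted p = 0.0383, and adjusted p = 0.743 with an estimated correlation) and did not pass at 4 weeks (adjusted p = 0.623) or at 8 weeks (adjusted p = 0.394). Of 20 adult sarcomere genes Myom2 rose by 1.06 and Tnni3 fell by 1.33, and the list had a median of 0.03, a negative mean of −0.18 and an adjusted p of 0.234. Of 6 skeletal muscle markers 3 fell and 1 rose at 8 weeks (list median −1.48, adjusted p = 0.0177, and adjusted p = 0.241 with an estimated correlation). That list call was lost without Klf9KI replicate 2 at 8 weeks (adjusted p = 0.118).

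For the per-age counts the 10 splits of 6 libraries are too few for a share under 0.05. The real count and the highest other were 266 and 151 at 1 week, 1945 and 0 at 4 weeks, 1518 and 0 at 8 weeks, 5828 and 0 for Wt-Cre hearts from 1 to 4 weeks and 3180 and 0 from 4 to 8 weeks.

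A first hypothesis was that the genotype effect runs against the change that control hearts make with age. Spearman's correlation across genes, which are not independent replicates, was −0.154 for the 8-week effect and the Wt-Cre change from 1 to 4 weeks, with a range of −0.235 to −0.080 over left-out libraries. It was −0.164 for the 4-week effect and the change from 1 to 8 weeks (−0.186 to −0.1) and 0.155 for the 1-week effect and the change from 4 to 8 weeks (0.095 to 0.175). These are small and of both signs, so they may reflect other things than maturation and do not settle the hypothesis. A second hypothesis was that genes lower at every age hold Klf9 regions more often than genes lower at a single age. Regions lay at 29 of 49 (59.2%) of the former and 398 of 848 (46.9%) of the latter (odds ratio 1.64, Fisher's exact test, two-sided, p = 0.106), which leaves it open.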
